A study of Homo sapiens with 6 samples.

How the data were processed

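Total RNA of 6 SK-MEL-2 samples was measured on Affymetrix oligonucleotide arrays, 1 array per sample, in 3 groups of 2 taken from the sample titles. The values deposited by the authors are probe set signals, a linear intensity, and the software that made them is not given in the sources used here. From the values, each array had been brought to 1 scale before deposit: the mean signal after trimming 2% of the probe sets at each end was 149.2 or 149.3 on every array, and the medians of the log2 values lay within 0.047 of each other. The values were therefore used as deposited, by a rule that allowed differences of up to 0.1 and otherwise called for quantile normalization. No detection calls were used here, so whether low signals were above background is unknown, and between 35.3% and 37% of the signals of an array lay below 16.

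The table held 22283 probe sets, of which 68 Affymetrix controls, with values on 1 array only, were left out. Of the 22215 used, 19065 had 1 gene symbol in the platform annotation, 1043 had several and 2107 had no gene listed, and genes were named only from probe sets with 1 symbol. Symbols were looked up by gene ID in a table of current human genes, where 99.9% of those probe sets matched and 0 symbols changed. These probe sets covered 11963 genes. Signals were turned into log2(signal + 16), and the lowest 40% of probe sets by mean over all arrays, with signals up to about 18.3, were left out of the tests. This left 13329 probe sets, 11880 of them with 1 symbol, for 7963 genes.

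Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). All 6 arrays entered 1 fit with a mean per group, since with 2 arrays per group the groups must share an estimate of the spread, which had 3 residual degrees of freedom. The 3 comparisons were the combination minus Ad-LacZ plus doxorubicin, the combination minus Ad-E2F-1 alone, and Ad-E2F-1 alone minus Ad-LacZ plus doxorubicin. Probe sets that passed the first and the second in the same direction were counted as differing from both single treatments. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and a probe set passed at an adjusted p under 0.05. Where comparisons shared arrays, their overlap of calls was set beside that of independent lists and beside 100 simulated data sets with unchanged groups. Every SE given with a log2 difference comes from this fit, and figures were drawn with matplotlib 3.10.9.

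Shifts of 24 gene lists were tested with camera from limma, two-sided, with a preset correlation of 0.01 and 1 probe set per gene, the one of highest mean. Their p-values were adjusted over 72 tests, 24 lists in 3 comparisons. The lists held G1/S and DNA replication, E2F and RB family, G2/M and mitosis, pro-apoptotic, anti-apoptotic, p53 target, DNA damage and repair, histone, interferon-stimulated, NF-kB and inflammatory, immediate early and AP-1, MAPK output, melanocyte lineage, unfolded protein and ATF4 response, heat shock, oxidative stress, sterol synthesis, extracellular matrix and TGF-beta, drug transport, oxidative phosphorylation and ribosomal protein genes, and markers of epithelial, fibroblast and immune cells. Of the 72 tests 15 were called, and 0 of these were called when camera estimated the correlation instead. List members are counted by the adjusted p over all probe sets and, separately, adjusted over the list alone.

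The groups, tests, lists, threshold, filter and other settings to try were fixed before the data were examined, as was the rule for named genes. That rule took the 10 largest rises and 10 largest falls per comparison among probe sets with 1 symbol that passed and whose groups did not overlap, up to 4 members of smallest p from each list discussed, the genes that differed from both single treatments, and a fixed set of further genes, of which those analysed here were E2F1, CCNE1, CCNE2, CDC6, CDKN1A, MDM2, TP73, APAF1, BCL2, MCL1 and MYC. Members of the G1/S, E2F and RB, G2/M, NF-kB, interferon, p53, oxidative stress and other lists named beyond these 4 were chosen after their values were seen. The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter or a filter of 60%, no trend, robust estimation, the replicate number as a block, fits of only the 2 groups compared, other thresholds, each array left out in turn, camera with an estimated correlation, fry, and means over the probe sets of a gene. Of the 6 fits that leave out an array, 2 drop an array of the group outside a given comparison. Such a fit changes no log2 difference of that comparison, only the estimate of the spread.

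Data were simulated with normal noise and the eBayes estimate of the spread of each probe set, which is drawn toward the intensity trend. Recovery and false calls under the unadjusted spread of each probe set were not tested. On these simulated data, with 200 changed probe sets among 13329, the procedure was tested before the comparisons were run. For the combination minus Ad-LacZ plus doxorubicin it recovered 19.7% of log2 differences of 0.5, 92.8% of differences of 1 and 100% of differences of 2. The shares were 20.9%, 92.5% and 100% for the combination minus Ad-E2F-1 alone, and 20.6%, 93.5% and 100% for Ad-E2F-1 alone minus Ad-LacZ plus doxorubicin. Between 6.2% and 11.3% of the calls were false, above the nominal rate, and camera called 2% of 200 unshifted lists of 7963 simulated genes at an unadjusted p under 0.05. The simulated genes varied independently and the lists were random, so this rate does not cover lists whose genes vary together.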

Results

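RNA was measured in SK-MEL-2 cells, a human melanoma cell line, after infection with an adenoviral vector at a multiplicity of infection of 2. Ad-E2F-1 is labelled as carrying E2F-1, a transcription factor that drives genes of S-phase entry and, in excess, apoptosis. Ad-LacZ carries a bacterial reporter gene and serves as the vector control. Doxorubicin, an anthracycline that poisons topoisomerase II and breaks DNA, was given at 0.1 uM. The 6 samples formed 3 groups of 2 arrays each: Ad-E2F-1 alone, Ad-E2F-1 plus doxorubicin (the combination), and Ad-LacZ plus doxorubicin. The samples of a group carry only a sample number, and nothing says that they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The median signal per array lay between 32.5 and 34.1, and the highest signal between 9137 and 10557. The number of arrays limits the precision, with a median standard error of 0.16 for a log2 difference. All signals below are means ± SD with n = 2, and differences are on the log2(signal + 16) scale, which understates the changes of genes with low signals.

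E2F1 itself, the gene of the vector, did not separate the groups. One E2F1 probe set read 148.5 and 167 on the arrays labelled Ad-E2F-1, 188.2 and 171.1 on those labelled Ad-E2F-1 plus doxorubicin, and 165.5 and 158.9 on those labelled Ad-LacZ plus doxorubicin. The other read 221 and 139.9, 173.5 and 162.7, and 145.9 and 173.6 in the same order. The E2F1 differences between the combination and Ad-LacZ plus doxorubicin were 0.13 ± 0.13 (SE) and 0.071 ± 0.19, with limma adjusted p-values of 0.707 and 0.907. Between Ad-E2F-1 alone and Ad-LacZ plus doxorubicin the E2F1 differences were -0.038 ± 0.13 and 0.13 ± 0.19 (adjusted p = 0.897 and 0.719). Between the combination and Ad-E2F-1 alone they were 0.17 ± 0.13 and -0.063 ± 0.19 (adjusted p = 0.559 and 0.907). The labels do not say which part of E2F1 the vector carries, so these probe sets do not check the labels. Group names below therefore stand for the arrays labelled so.

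The first comparison asked what Ad-E2F-1 changed relative to the control vector when each was given with doxorubicin. On the arrays labelled Ad-E2F-1 plus doxorubicin, 8 of 51 measured G1/S and DNA replication genes were higher than on those labelled Ad-LacZ plus doxorubicin, and the shift of their list did not pass with an estimated correlation (camera adjusted p = 0.0513). CCNE1, the cyclin E1 that activates CDK2 at the start of S phase, read 282.7 ± 17.1 against 81.4 ± 0.71, a rise of 1.62 ± 0.13 (SE) in log2 (limma adjusted p = 0.000411). CCNE2, the second cyclin E, read 495.5 ± 68.7 against 135.1 ± 19.7, a rise of 1.76 ± 0.15 (adjusted p = 0.000411). E2F8, an atypical E2F that represses transcription, rose by 1.52 ± 0.16 from 111.3 ± 8.91 to 352.2 ± 79.3 (adjusted p = 0.00117). MYB, a transcription factor of proliferating progenitor cells, rose by 1.68 ± 0.15, from 33.5 ± 6.58 to 141.5 ± 5.52 (adjusted p = 0.000678).

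**Figure D1:**
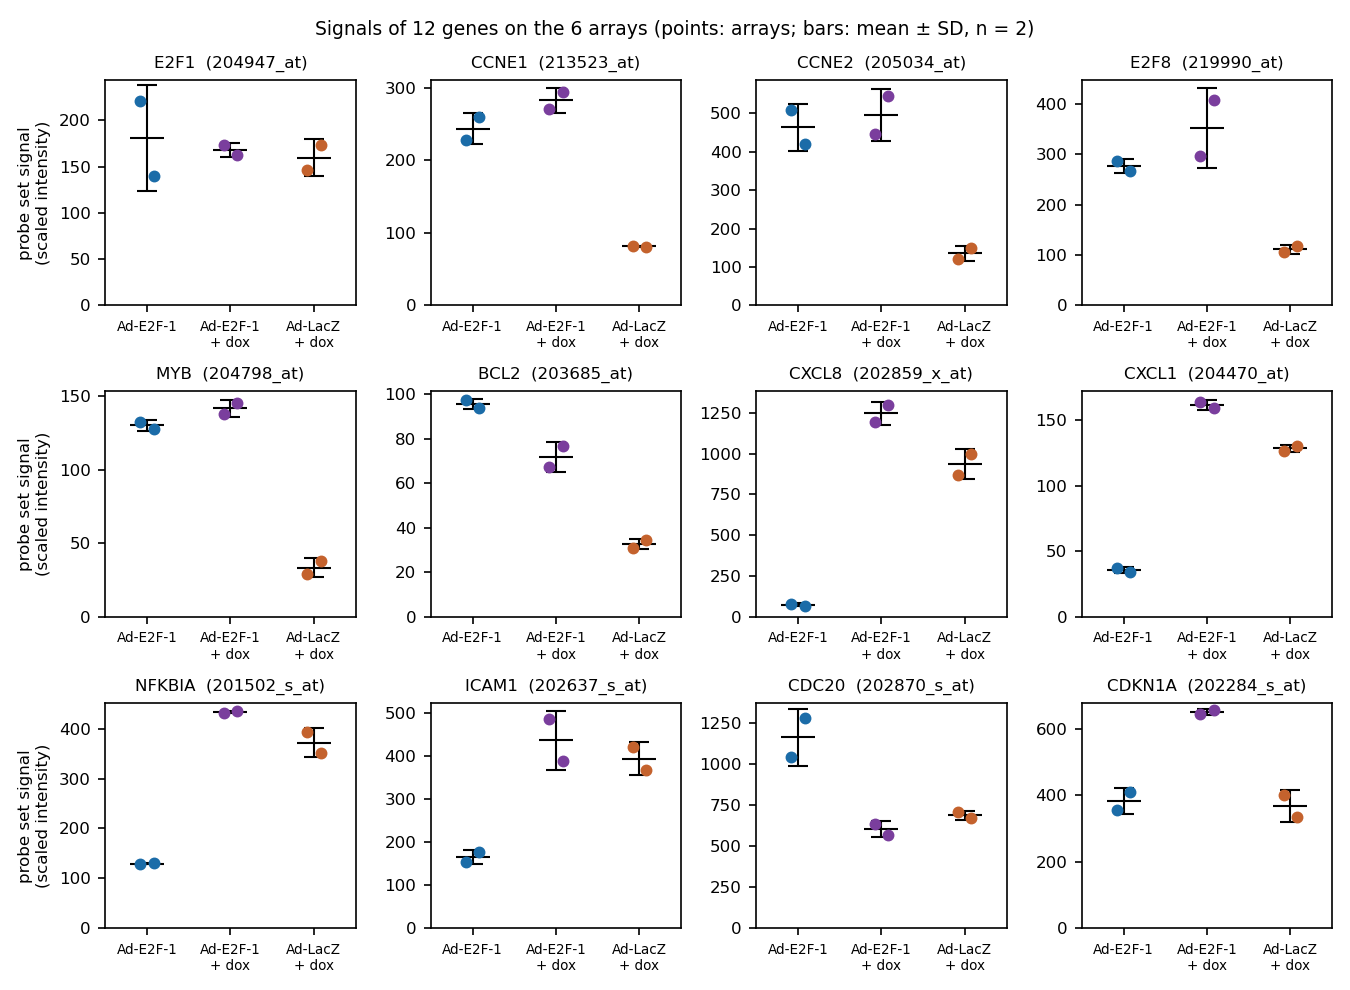
Probe set signals (scaled intensity, linear axis from 0) of 12 genes on the 6 arrays by group, with points for arrays and bars for mean ± SD (n = 2), using each gene's tested probe set of highest signal. CCNE2 averaged 464.2 with Ad-E2F-1, 495.5 with Ad-E2F-1 plus doxorubicin and 135.1 with Ad-LacZ plus doxorubicin, CXCL8 averaged 74.7, 1247 and 934.6 in the same order, and E2F1 lay between 139.9 and 221 on all arrays.

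In total 168 of 13329 probe sets passed the threshold in this comparison, 150 of them higher with Ad-E2F-1 (121 genes) and 18 lower (16 genes), and 1776 had an unadjusted p under 0.05. The other large rises were EPB41L4B, a FERM-domain protein of the membrane cytoskeleton (1.92), SYNGR3, a synaptic vesicle protein (1.42), SAC3D1 (1.41), the receptor tyrosine kinase FGFR3 (1.35), CCNO (1.34) and HPGD, which degrades prostaglandins (1.33). The largest falls were CFAP45 (-1.15), CCDC86 (-1.0), the Polycomb component PCGF1 (-1.0), RAP1GAP2 (-0.96), the zinc finger factor KLF6 (-0.88), the connexin gene GJA5 (-0.81), PAK1IP1 (-0.79), the collagen receptor DDR2 (-0.77), the thioredoxin-binding protein gene TXNIP (-0.74) and MIEF1 (-0.67). No other tested probe set of FGFR3, HPGD, PCGF1, TXNIP or MIEF1 passed in the same direction. Of the probe sets that passed, 16 list several genes or none here and are not named, and 3 of these, at 1.78 to 1.83, rose by more than CCNE2. On 1 side of the comparison SYNGR3, HPGD, HRK and CFAP45 (8.75 ± 0.64 in the combination) had a mean signal below the filter level of 18.3, so whether that side was above background is unknown and the size of these differences depends on the pseudocount. Leaving out an array of Ad-E2F-1 alone changes no log2 difference in this comparison, only the estimate of the spread. The count was 104 and 105 without Ad-E2F-1 replicate 1 or 2, 80 and 68 without replicate 1 or 2 of the combination, and 59 and 63 without replicate 1 or 2 of Ad-LacZ plus doxorubicin. RAP1GAP2, DDR2, TXNIP, MIEF1, BCL2 and ABHD3 passed in 0 of these 6 fits, GJA5, PAK1IP1, IDH2, KLF10, FN1 and MARCKS in 1, CFAP45 in 2, HPGD, PCGF1, KLF6 and CDKN1A in 3, CCNO in 4, SYNGR3 in 5, and CCNE1, CCNE2, MYB, E2F8, EPB41L4B, SAC3D1, FGFR3 and CCDC86 in all 6.

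By list, 8 of the 51 measured G1/S and DNA replication genes, a set rich in E2F targets, rose with Ad-E2F-1 in the presence of doxorubicin and 0 fell, with 21 rises and 0 falls adjusted over the list alone. The list median was 0.26 and 47 of 51 members were positive (camera adjusted p = 9.48e-16, and adjusted p = 0.0513 with an estimated correlation). Besides the cyclins E, its rises included SLBP, the histone mRNA binding protein (0.84 ± 0.096, from 616.2 ± 38.0 to 1111 ± 14.4), and PCNA, the sliding clamp of replication (0.51 ± 0.089, from 1531 ± 21.5 to 2182 ± 11.03). DBF4, CDC25A, MCM6 and UNG rose by 0.65, 0.81, 0.53 and 0.62. CDC6, a replication licensing factor, differed by 0.32 ± 0.11 and 0.39 ± 0.17 on its 2 probe sets and did not pass (adjusted p = 0.25 and 0.348). In the E2F and RB family list 4 of 16 genes rose and 0 fell, with 6 and 0 adjusted over the list alone (median 0.28, camera adjusted p = 0.000176, and adjusted p = 0.134 with an estimated correlation). Apart from E2F8 these were cyclin D3, CCND3 (1.07 ± 0.15), and the CDK inhibitor genes CDKN2A (0.79 ± 0.12) and CDKN1B (0.75 ± 0.15), so the list's rises held a cyclin and inhibitors of cyclin-dependent kinases together. Of 61 G2/M and mitosis genes 3 rose and 0 fell, 11 and 0 adjusted over the list alone (median 0.16, camera adjusted p = 5.46e-07, and adjusted p = 0.0819 with an estimated correlation). The 3 were the spindle protein gene NUSAP1 (0.77 ± 0.10), CCNF (0.91 ± 0.15) and the kinetochore gene NDC80 (0.59 ± 0.12).

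Genes of cell death and of the p53 response moved singly in this comparison, and their lists were not called. HRK, a BH3-only activator of apoptosis, rose by 1.08 ± 0.19 from 14.5 ± 1.98 to 48.3 ± 0.99 (adjusted p = 0.0273), the 1 rise against 0 falls among 29 pro-apoptotic genes, with 2 and 0 adjusted over the list alone (median -0.001, mean 0.091, camera adjusted p = 0.623). BCL2, which blocks apoptosis, rose by 0.85 ± 0.16 from 32.7 ± 2.26 to 71.9 ± 6.72 (adjusted p = 0.033, passing in 0 of the 6 fits that left out an array), the 1 rise among 10 anti-apoptotic genes and the 1 adjusted over the list alone (median -0.11, camera adjusted p = 0.776). The other 3 BCL2 probe sets lay below the signal filter. CDKN1A, which encodes the CDK inhibitor p21, was the 1 rise among 30 p53 target genes, with 3 and 0 adjusted over the list alone (median -0.012, mean 0.11 and an upward camera direction, adjusted p = 0.191). The differences for APAF1 (0.17 ± 0.20 and 0.14 ± 0.20) and MYC (-0.32 ± 0.19) did not pass, and the 5 MCL1 probe sets ranged from -0.32 to 0.42 with mixed signs and did not pass either. MDM2 and TP73 were below the filter on every probe set and were not tested. Single members of other lists that rose were CD83 (1.11 ± 0.12, NF-kB and inflammatory list), the sterol synthesis genes IDI1 (1.09 ± 0.11) and INSIG1 (0.87 ± 0.15), the interferon-stimulated gene HERC5 (0.70 ± 0.13), the chaperone gene DNAJB9 (0.68 ± 0.13), the immediate early gene KLF10 (0.60 ± 0.12), ID3 (0.56 ± 0.11) and the repair gene PARP2 (0.53 ± 0.11). Their lists were not called, with camera adjusted p-values of 0.873 for NF-kB and inflammatory genes, 0.0608 for sterol synthesis, 0.191 for interferon-stimulated genes, 0.988 for the unfolded protein list of DNAJB9, 0.231 for the immediate early list of KLF10, 0.445 for the extracellular matrix list of ID3 and 0.0969 for DNA damage and repair, nor were oxidative phosphorylation (0.127) and melanocyte lineage genes (0.867).

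The second comparison asked what doxorubicin changed when added to Ad-E2F-1. On the arrays labelled Ad-E2F-1 plus doxorubicin, 8 of 22 NF-kB and inflammatory genes were higher and 9 of 61 G2/M and mitosis genes lower than on those labelled Ad-E2F-1. The shifts of these lists did not pass with an estimated correlation (camera adjusted p = 0.114 and 0.0513). CXCL8, the neutrophil chemokine interleukin 8, rose by 3.8 ± 0.12 (SE) in log2, from 74.7 ± 9.26 to 1247 ± 71.8 (limma adjusted p = 1.63e-07). NFKBIA, the inhibitor that NF-kB itself induces, rose by 1.63 ± 0.12, from 129.4 ± 1.20 to 433.2 ± 2.62 (adjusted p = 0.000132), and the chemokine CXCL1 by 1.78 ± 0.14, from 35.7 ± 2.33 to 161.6 ± 3.61 (adjusted p = 0.00026). PLK1, a kinase of mitotic entry, went from 607.2 ± 94.3 to 192.2 ± 82.2, a log2 difference of -1.63 ± 0.22 (adjusted p = 0.0092), and CCN2, a matricellular growth factor, from 650.2 ± 23.7 to 182.1 ± 21.8, a difference of -1.75 ± 0.12 (adjusted p = 0.000132).

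In total 191 probe sets passed, 89 higher with doxorubicin added (71 genes) and 102 lower (80 genes), and 2177 had an unadjusted p under 0.05. Further large rises were INHBA, a subunit of activin A (1.80), DEPP1 (1.36), the adhesion molecule ICAM1 (1.31), CRISPLD2 (1.23), the pentraxin PTX3 (1.22), the interleukin 9 receptor gene IL9R (1.15) and the adaptor TRAF1 (1.14). Further large falls were the laminin chain LAMA4 (-1.52), the phosphatase PPM1F (-1.25), CFAP45 (-1.15), DEPDC1 (-1.11), the protein kinase C substrate MARCKS (-1.10), AMOTL2, an angiomotin (-1.08), the membrane metalloproteinase MMP14 (-1.06) and TRIO (-1.01). An unnamed probe set rose by 2.21, more than INHBA. On 1 side of the comparison INHBA, DEPP1, IL9R, LAMA4, PPM1F, CFAP45 and TRIO had a mean signal below the filter level of 18.3. Another tested probe set of LAMA4 and another of TRIO had the opposite sign, and no other probe set of DEPP1, PPM1F or MMP14 passed in the same direction. The count was 24 and 28 without Ad-E2F-1 replicate 1 or 2, and 44 and 108 without replicate 1 or 2 of the combination. IL9R and KLF10 passed in 0 of the 6 fits that left out an array, IDH2 in 1, PPM1F, CFAP45, MMP14, TRIO, ABHD3, CDKN1A, PAK1IP1 and FN1 in 2, DEPP1, TRAF1, LAMA4, DEPDC1 and EPB41L4B in 3, CRISPLD2 and KLF6 in 4, PLK1 in 5, and CXCL8, CXCL1, NFKBIA, ICAM1, INHBA, PTX3, CCN2, MARCKS and AMOTL2 in all 6.

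By list, 8 of 22 NF-kB and inflammatory genes rose when doxorubicin was added and 0 fell, with 15 and 0 adjusted over the list alone (median 0.60, camera adjusted p = 4.26e-11, and adjusted p = 0.114 with an estimated correlation). Beside the chemokines, NFKBIA, ICAM1 and TRAF1, these were TNFAIP3, a deubiquitinase that restrains NF-kB (0.89 ± 0.14), NFKB2 (0.80 ± 0.17) and the macrophage growth factor CSF1 (1.07 ± 0.22). Of 61 G2/M and mitosis genes 9 fell and 0 rose, with 25 falls and 1 rise adjusted over the list alone (median -0.28, camera adjusted p = 7.22e-14, and adjusted p = 0.0513 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, went from 1162 ± 170.8 to 602.2 ± 48.2 (-0.92 ± 0.12), cyclin B1, CCNB1, from 1460 ± 1.49 to 862.4 ± 85.2 (-0.75 ± 0.10), and the kinesin KIF20A from 633.4 ± 83.7 to 344.6 ± 20.2 (-0.84 ± 0.13). WEE1, AURKA, CKS2, CENPA and TPX2 were the other members that fell. In contrast to the mitotic list, 0 of 51 G1/S and DNA replication genes passed in either direction, with 2 rises and 1 fall adjusted over the list alone. That list had a median of 0.016 and a mean of 0.012 against a downward camera direction (adjusted p = 0.867). CCNE1 (0.20 ± 0.13) and CCNE2 (0.091 ± 0.15 and -0.014 ± 0.13) did not pass, nor did CDC6 (0.13 ± 0.11 and 0.18 ± 0.17) or any of the 16 E2F and RB family genes, of which 1 fell adjusted over the list alone (median -0.064, camera adjusted p = 0.421).

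Oxidative phosphorylation genes shifted upward as a list when doxorubicin was added, with 49 of 53 members positive and a median of 0.14, although 0 members passed singly, over all probe sets or adjusted over the list alone (camera adjusted p = 2.81e-05, and adjusted p = 0.11 with an estimated correlation). Among 33 interferon-stimulated genes 1 rose and 0 fell, 8 and 0 adjusted over the list alone (median 0.23, camera adjusted p = 0.0035, and adjusted p = 0.425 with an estimated correlation). The 1 was PSMB9, a subunit of the immunoproteasome (0.82 ± 0.15). Among 22 melanocyte lineage genes 1 fell and 0 rose, 4 and 0 adjusted over the list alone (median -0.071, camera adjusted p = 0.0159, and adjusted p = 0.267 with an estimated correlation), and the list was not called without replicate 2 of the combination (adjusted p = 0.129). The 1 was SOX10, a lineage transcription factor, which went from 431.6 ± 10.1 to 266.6 ± 20.7 (-0.67 ± 0.11), while MITF, the master regulator of the lineage, differed by -0.55 ± 0.14 and did not pass (adjusted p = 0.0887).

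Among p53 target genes 2 of 30 rose with doxorubicin added and 0 fell, the same counts as adjusted over the list alone (median 0.090, camera adjusted p = 0.191). They were CDKN1A (0.75 ± 0.12) and the death receptor gene TNFRSF10B, which rose by 0.85 ± 0.12 from 278.5 ± 8.70 to 514.5 ± 50.8. TNFRSF10B was also the 1 rise among 29 pro-apoptotic genes, and the 1 adjusted over the list alone (median 0.065, camera adjusted p = 0.623). Among 10 anti-apoptotic genes 0 passed over all probe sets and 1 rose adjusted over the list alone (median -0.18, camera adjusted p = 0.213), with BCL2 at -0.35 ± 0.16 (adjusted p = 0.311). MYC (-0.48 ± 0.19), the APAF1 probe sets (-0.023 ± 0.20 and 0.14 ± 0.20) and the MCL1 probe sets (-0.43 to 0.12) did not pass. In the DNA damage and repair list 0 of 53 rose and 2 fell, as adjusted over the list alone (median -0.006, camera adjusted p = 0.264). These were H2AX, the histone variant phosphorylated at breaks (-0.93 ± 0.17), and XRCC4, a factor of end joining (-0.69 ± 0.14). The extracellular matrix and TGF-beta list had 1 rise, INHBA, and 3 falls, CCN2, CCN1 (-0.97 ± 0.11) and THBS1 (-0.70 ± 0.12), and 3 of each adjusted over the list alone (median -0.013, camera adjusted p = 0.515). Among 31 oxidative stress genes 3 fell and 0 rose, and 4 of each passed adjusted over the list alone (median 0.094, camera adjusted p = 0.783). All 3 were metallothioneins, metal-binding proteins: MT1H (-0.63 ± 0.092), MT1X (-0.77 ± 0.13) and MT1F (-0.61 ± 0.12).

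**Figure D2:**
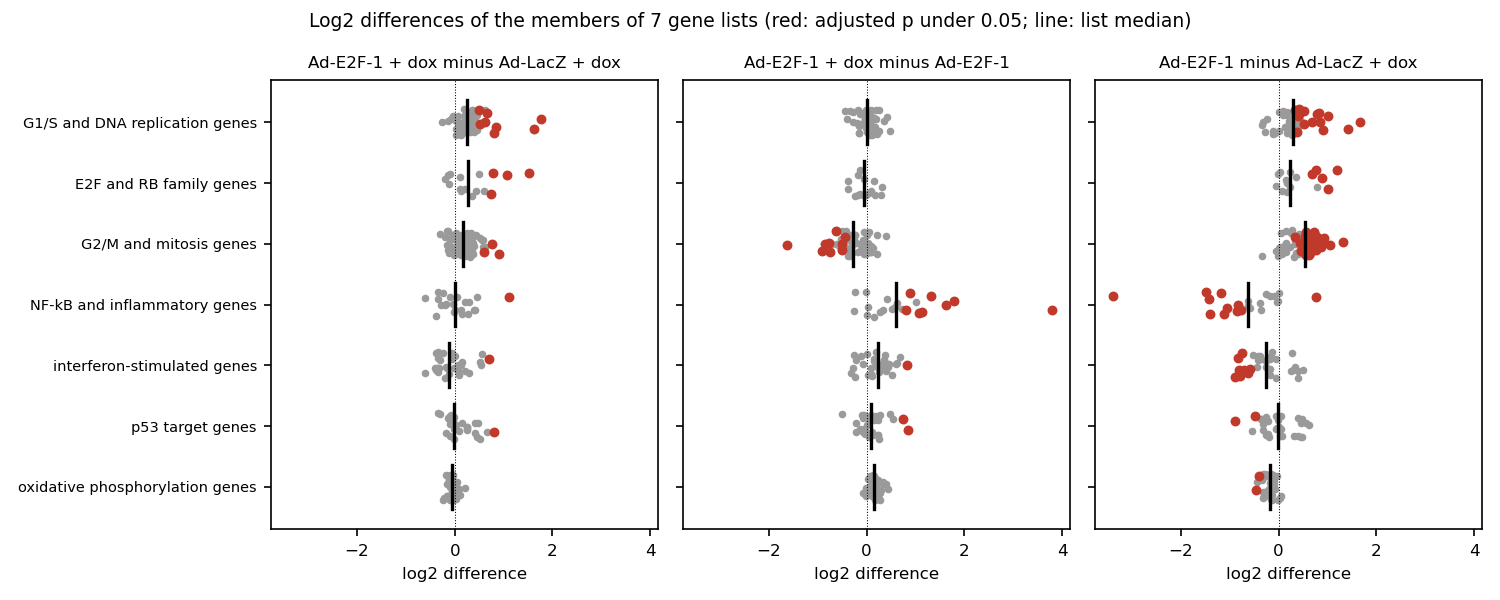
Log2 differences of the measured members of 7 gene lists in the 3 comparisons, 1 point per gene, with members past the adjusted p threshold in red and a line at each list median. The G2/M median was 0.16, -0.28 and 0.53 from left to right, the NF-kB median 0.00, 0.60 and -0.62, and the G1/S median 0.26, 0.016 and 0.29.

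The third comparison set the single treatments against each other, Ad-E2F-1 alone against Ad-LacZ plus doxorubicin, so vector and drug differed at once. Rises and falls in this comparison are given for Ad-E2F-1 alone relative to Ad-LacZ plus doxorubicin. By itself it cannot assign them to the vector or to the absence of the drug. On the arrays labelled Ad-E2F-1 alone, 31 of 61 G2/M and mitosis genes and 15 of 51 G1/S and DNA replication genes were higher, and 10 of 22 NF-kB and inflammatory genes lower. The shifts of these 3 lists did not pass with an estimated correlation (camera adjusted p = 0.0513, 0.0605 and 0.134). CCNE2 was higher by 1.67 ± 0.15 (SE) in log2 (464.2 ± 61.2 against 135.1 ± 19.7, limma adjusted p = 0.000525) and CCNE1 by 1.41 ± 0.13 (243.8 ± 21.7 against 81.4 ± 0.71, adjusted p = 0.000525). CXCL8 read 74.7 ± 9.26 against 934.6 ± 91.7, a difference of -3.39 ± 0.12 (adjusted p = 5.32e-07). DCK, the kinase that activates deoxycytidine, read 479.7 ± 7.50 against 168 ± 9.97, a difference of 1.43 ± 0.12 (adjusted p = 0.0003).

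In total 832 probe sets passed, 481 higher with Ad-E2F-1 alone (366 genes) and 351 lower (289 genes), and 3081 had an unadjusted p under 0.05. The other large rises were RHOBTB2 (1.80), MYB (1.57), the linker histone gene H1-10 (1.36), SAC3D1 (1.34), PLK1 (1.32), CCN2 (1.29) and the kinesin KIFC1 (1.28). The other large falls were INHBA (-1.98), DEPP1 (-1.80), ZNF335 (-1.54, with 34.4 ± 33.2 against 115.2 ± 27.2), CXCL1 (-1.48), TRAF1 (-1.43), NFKBIA (-1.41), the deubiquitinase OTUB2 (-1.35), SNAPC4 (-1.33) and CRISPLD2 (-1.25). An unnamed probe set lay at -2.80, further down than INHBA, and another at 1.79. On 1 side of the comparison RHOBTB2, INHBA, DEPP1, OTUB2 and HRK had a mean signal below the filter level of 18.3. The other tested probe set of DEPP1 and that of SNAPC4 did not pass in the same direction. The count was 178 and 194 without Ad-E2F-1 replicate 1 or 2, and 299 and 319 without replicate 1 or 2 of Ad-LacZ plus doxorubicin. Of the 6 fits that left out an array, ZNF335 passed in 3, H1-10 in 4 and PLK1 in 5, and CCNE1, CCNE2, CXCL8, DCK and the other large rises and falls named here in all 6.

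By list, 31 of 61 G2/M and mitosis genes were higher with Ad-E2F-1 alone than with Ad-LacZ plus doxorubicin and 0 lower, 45 and 1 adjusted over the list alone (median 0.53, camera adjusted p = 2.15e-22, and adjusted p = 0.0513 with an estimated correlation). Examples were the kinesin KIF14 (1.05 ± 0.14), NDC80 (0.92 ± 0.12), the spindle midzone gene PRC1 (0.74 ± 0.097) and the mitotic kinase gene AURKA (0.70 ± 0.096). In the G1/S and DNA replication list 15 of 51 rose and 0 fell, 23 and 1 adjusted over the list alone (median 0.29, camera adjusted p = 4.26e-11, and adjusted p = 0.0605 with an estimated correlation), among them SLBP (1.00 ± 0.096), the uracil glycosylase gene UNG (0.90 ± 0.12) and RRM2, a subunit of ribonucleotide reductase (0.39 ± 0.091). CDC6 did not pass (0.19 ± 0.11 and 0.21 ± 0.17). In the E2F and RB family list 5 of 16 rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.23, camera adjusted p = 2.81e-05, and adjusted p = 0.126 with an estimated correlation). They were E2F8 (1.20 ± 0.16), CCND3 (0.77 ± 0.15) and the CDK inhibitor genes CDKN2A (1.02 ± 0.12), CDKN2D (0.88 ± 0.16) and CDKN1B (0.69 ± 0.15). In the DNA damage and repair list 4 of 53 rose and 0 fell, the same counts as adjusted over the list alone (median 0.086, camera adjusted p = 0.0159, and adjusted p = 0.214 with an estimated correlation). These were H2AX (1.19 ± 0.17), PARP2 (0.80 ± 0.11), the mismatch repair gene MSH6 (0.42 ± 0.092) and BARD1, the partner of BRCA1 (0.73 ± 0.16).

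In the NF-kB and inflammatory list 10 of 22 were lower with Ad-E2F-1 alone than with Ad-LacZ plus doxorubicin and 1 was higher, 12 and 1 adjusted over the list alone (median -0.62, camera adjusted p = 2.77e-08, and adjusted p = 0.134 with an estimated correlation). The lower genes included ICAM1 (-1.18 ± 0.14), the cytokine IL6 (-1.11 ± 0.19) and NFKB2 (-1.05 ± 0.17), and the 1 higher gene was CD83 (0.77 ± 0.12). Between the vectors with doxorubicin in both groups the list median was 0, with 1 gene higher and 0 lower. Adding doxorubicin to Ad-E2F-1 gave a list median of 0.60, with 8 genes higher and 0 lower. Of 33 interferon-stimulated genes 9 fell and 0 rose, 15 and 1 adjusted over the list alone (median -0.27, camera adjusted p = 0.000875, and adjusted p = 0.377 with an estimated correlation), among them the RNA sensor RIGI (-0.89 ± 0.16) and ISG15 (-0.72 ± 0.16). Of 53 oxidative phosphorylation genes 2 fell and 0 rose, and 0 passed adjusted over the list alone (median -0.17, camera adjusted p = 5.46e-07, and adjusted p = 0.0819 with an estimated correlation), the 2 being NDUFA2 (-0.39 ± 0.093) and ATP5MC1 (-0.45 ± 0.11). BCL2 rose by 1.20 ± 0.16, from 32.7 ± 2.26 to 95.6 ± 2.26 (adjusted p = 0.0033), and BIRC2, an inhibitor of apoptosis protein, differed by -0.38 ± 0.090 (adjusted p = 0.0351), the 2 calls among 10 anti-apoptotic genes, of which 2 rose and 1 fell adjusted over the list alone (median -0.022, mean 0.10, camera adjusted p = 0.783). Of 29 pro-apoptotic genes 2 rose, the kinase gene MAP3K5 (0.76 ± 0.18) and HRK (0.76 ± 0.19), and 1 fell, TNFRSF10B (-0.89 ± 0.12), against 3 and 1 adjusted over the list alone (median 0.005, camera adjusted p = 0.988). Of 30 p53 target genes 0 rose and 2 fell, TNFRSF10B and EPHA2 (-0.48 ± 0.12), and 3 of each passed adjusted over the list alone (median -0.022, camera adjusted p = 0.988). CDKN1A (0.053 ± 0.12), MYC (0.16 ± 0.19), the APAF1 probe sets (0.20 ± 0.20 and 0.005 ± 0.20) and the MCL1 probe sets (-0.12 to 0.29) did not pass.

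The comparisons share arrays. Of the probe sets higher in the combination than with Ad-LacZ plus doxorubicin, 124 were also higher with Ad-E2F-1 alone than with Ad-LacZ plus doxorubicin, and 8 were lower in both. Independent lists of these sizes would share 5.41 and 0.47, and simulated unchanged groups shared 0.02 on average in each direction. Against Ad-E2F-1 alone, 69 probe sets were higher and 52 lower in both doxorubicin groups, where independent lists would share 2.34 and 3.68 and simulated unchanged groups shared 0 and 0.02. The simulated value holds chance without any effects, and that of independent lists leaves out the shared arrays, so neither gives the overlap to be looked for between comparisons that hold effects and share arrays. These overlaps were chosen after the data were seen, and part of the excess may come from the shared arrays. The overlaps were not recounted with separate arrays in each comparison.

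The last comparison asked which genes differed in the combination from both single treatments in the same direction. The clearest was GCH1, the first enzyme of tetrahydrobiopterin synthesis, at 616.2 ± 10.8 in the combination against 301.7 ± 15.8 with Ad-E2F-1 alone and 295.9 ± 4.95 with Ad-LacZ plus doxorubicin. Its rises were 0.99 ± 0.11 and 1.02 ± 0.11 (SE) in log2 (limma adjusted p = 0.00254 and 0.00141). CDKN1A read 651 ± 9.62 against 382.2 ± 39.2 and 368.4 ± 47.5, rises of 0.75 ± 0.12 and 0.80 ± 0.12 (adjusted p = 0.0211 and 0.0137). EPB41L4B, the phospholipase gene ABHD3, the mitochondrial isocitrate dehydrogenase gene IDH2 and the TGF-beta-inducible factor gene KLF10 were also higher than with either single treatment. The genes lower than with either were CFAP45, at 8.75 ± 0.64 against 39.1 ± 5.02 and 39.1 ± 2.69, KLF6, PAK1IP1, the fibronectin gene FN1 and MARCKS. The CFAP45 signal in the combination lay below the filter level of 18.3, and whether it was above background is unknown. Another FN1 probe set had the opposite sign against Ad-LacZ plus doxorubicin, 0 of the 5 other FN1 probe sets passed in the same direction, and the other IDH2 probe set did not pass. The other KLF6 probe set passed against Ad-E2F-1 alone but not against Ad-LacZ plus doxorubicin, and of the 3 other MARCKS probe sets 1 and 0 did.

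**Figure D3:**
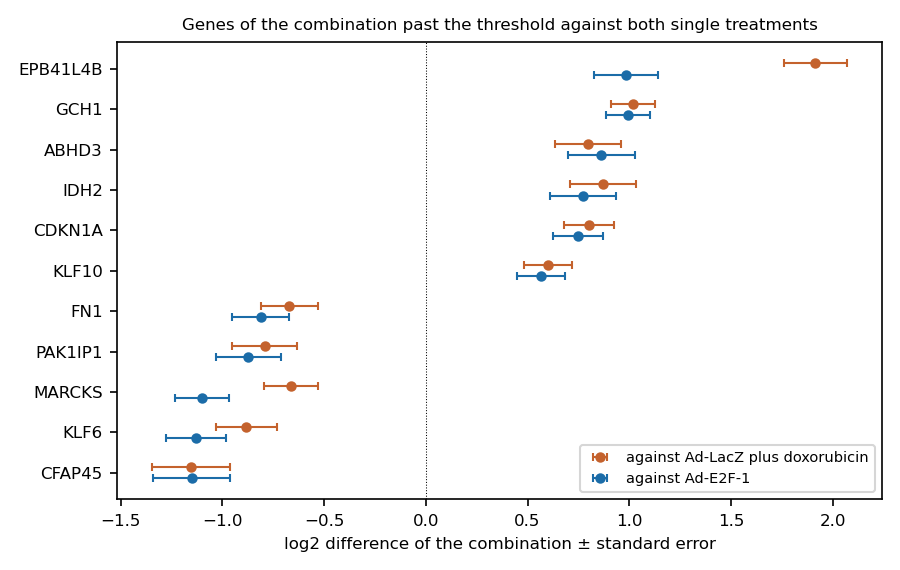
Log2 differences ± standard error of the combination from Ad-LacZ plus doxorubicin and from Ad-E2F-1 alone, for the 11 named genes past the threshold against both. EPB41L4B lay at 1.92 and 0.98, GCH1 at 1.02 and 0.99, and CFAP45 at -1.15 in each.

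Of the 6 fits that left out an array, GCH1 passed in 6 against Ad-E2F-1 alone and 6 against Ad-LacZ plus doxorubicin. In that order CDKN1A passed in 2 and 3, EPB41L4B in 3 and 6, ABHD3 in 2 and 0, IDH2 in 1 and 1, and KLF10 in 0 and 1. CFAP45 passed in 2 and 2, KLF6 in 4 and 3, PAK1IP1 in 2 and 1, FN1 in 2 and 1, and MARCKS in 6 and 1. Leaving out an array of the group outside a comparison cannot change the log2 differences of that comparison, only the estimate of the spread. In all 12 probe sets differed from both single treatments in the same direction, 7 higher (1 of them unnamed) and 5 lower. Independent lists of these sizes would share 1 and 0.14, and simulated unchanged groups sharing the combination arrays gave 0.01 and 0.03 on average and at most 1. The same limits hold for these values, so the excess over them does not measure a joint effect. Part of the excess may come from the shared combination arrays, and the count was not repeated with separate combination arrays in each comparison. The count was 2 without either Ad-E2F-1 replicate 1 or 2, 5 without replicate 1 of the combination, and 5 and 6 without replicate 1 or 2 of Ad-LacZ plus doxorubicin. No group had neither treatment or Ad-LacZ alone, so whether the treatments acted more than additively was not testable here.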

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

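The fits of only 2 groups with crossed and uncrossed replicate numbers were added after the data were seen. Calls of named genes were followed through the settings for 3 sets only. These were the largest rises and falls, the genes that differed from both single treatments, and the fixed set of further genes. Calls of other list members, such as HRK, SLBP or SOX10, were not followed, so how they depend on the processing is unknown. No called result changed direction, the scalings moved the median difference of all probe sets by at most 0.031 in size, and pseudocounts of 1 and 64, robust estimation and a 60% filter left all 4 counts within 1.5 times. The counts below are given in the order combination minus Ad-LacZ plus doxorubicin, combination minus Ad-E2F-1, Ad-E2F-1 minus Ad-LacZ plus doxorubicin, and same direction against both, where 168, 191, 832 and 12 were reported. Testing all probe sets gave 39, 23, 307 and 2, with more dim probe sets in the adjustment and in the shared spread, and leaving out the intensity trend gave 51, 21, 321 and 3, where the cause was not tested. An adjusted p under 0.1 gave 331, 446, 1577 and 38, and requiring a 2-fold difference 40, 39, 98 and 1. Median centring gave 7 for both, the cause was not tested, and quantile normalization 13, of which 9 were higher and 4 lower against 7 and 5 as deposited. A fit of only the 2 groups compared gave 109 for the first, with 2 residual degrees of freedom. Fits without 1 array, in which the lone array of a group is assumed to vary like the others, gave 59 to 105 for the first (104 and 105 without Ad-E2F-1 replicates 1 and 2, 80 and 68 without those of the combination, 59 and 63 without those of Ad-LacZ plus doxorubicin), 24 to 184 for the second (24, 28, 44 and 108 without the Ad-E2F-1 and combination replicates), 178 to 982 for the third (178 and 194 without the Ad-E2F-1 replicates, 299 and 319 without those of Ad-LacZ plus doxorubicin) and 2 to 9 for both (2 and 2, 5 and 9, 5 and 6 in the same order of arrays). Of 80 calls of named genes 39 were kept without each array in turn, 64 under both scalings, both pseudocounts and the block, and 0 changed sign.

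The labels do not say whether the replicate numbers pair the samples. The replicate deviations correlated at -0.096 between Ad-E2F-1 and the combination, -0.214 between Ad-E2F-1 and Ad-LacZ plus doxorubicin, and 0.116 between the latter and the combination. With the number as a block the first count was 111 and the count against both 7, and the block changed no list's call. Crossing the numbers, in a fit of only the 2 groups, gave 2879 calls for Ad-E2F-1 minus Ad-LacZ plus doxorubicin, against 713 with the numbers as given. A batch shared between groups under other numbers is therefore not excluded.

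With an estimated correlation camera called 0 of the 15 list shifts. Whether this came from correlation between genes or from the few residual degrees of freedom was not tested. The adjusted p-values for the combination minus Ad-LacZ plus doxorubicin were 0.0513 (G1/S), 0.134 (E2F and RB) and 0.0819 (G2/M). For the combination minus Ad-E2F-1 they were 0.0513 (G2/M), 0.425 (interferon), 0.114 (NF-kB), 0.267 (melanocyte) and 0.11 (oxidative phosphorylation). For Ad-E2F-1 minus Ad-LacZ plus doxorubicin they were 0.0605 (G1/S), 0.126 (E2F and RB), 0.214 (DNA damage), 0.0513 (G2/M), 0.377 (interferon), 0.134 (NF-kB) and 0.0819 (oxidative phosphorylation). Fry, which asks whether members move 1 way on balance and compares them with no other genes, did not call the interferon (0.0701) and melanocyte lists (0.167) for the combination minus Ad-E2F-1. It called 6 list tests that camera did not: DNA damage (0.0315) and MAPK output (0.0146) in the first comparison, anti-apoptotic (0.0294) and MAPK output (0.0374) in the second, and anti-apoptotic (0.0294) and immediate early (0.0374) in the third. DNA damage was also called in the first with a 60% filter (0.0377) and MAPK output with means over probe sets (0.0461), where the cause was not tested. Without 1 array the melanocyte list ranged from 0.00941 to 0.129 in the second comparison, its highest without replicate 2 of the combination. The DNA damage list ranged from 0.0368 (without replicate 1 of the combination) to 0.464 in the first, and the sterol list from 0.0136 to 0.317 in the first (0.0141 without replicate 2 of the combination, 0.0136 without replicate 1 of Ad-LacZ plus doxorubicin) and from 0.0472 (the latter array) to 0.309 in the third. Ribosomal protein genes ranged from 2.99e-05 to 0.803 in the first (2.99e-05 without replicate 1 of the combination, 0.000129 without replicate 1 of Ad-LacZ plus doxorubicin), from 0.00164 (without replicate 2 of the combination) to 1 in the second, and from 0.000121 to 0.866 in the third (0.0316 without Ad-E2F-1 replicate 1, 0.0242 and 0.0232 without replicates 1 and 2 of the combination, 0.000121 without replicate 1 of Ad-LacZ plus doxorubicin). Low signals limit the results that rest on dim probe sets, since no measure of background was used here.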

Other observations

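Of the tests below, those of the E2F1 probe sets and of the G1/S against the G2/M list were chosen after the result was seen. Groups not yet described had single members that passed. In the oxidative stress list 3 of 31 genes rose with Ad-E2F-1 alone against Ad-LacZ plus doxorubicin and 5 fell, 4 and 7 adjusted over the list alone (median -0.12, camera adjusted p = 0.325). The metallothionein genes MT1H (0.53 ± 0.092) and MT1X (0.65 ± 0.13) rose, and the autophagy receptor gene SQSTM1 (-0.65 ± 0.10) and OSGIN1 (-0.92 ± 0.19) fell. Of 37 unfolded protein and ATF4 response genes 3 fell there and 0 rose, as adjusted over the list alone (median 0.013, mean -0.003 and a downward camera direction, adjusted p = 0.988): the chaperone genes HSPA5 (-0.46 ± 0.096) and CALR (-0.69 ± 0.18), and VEGFA (-0.55 ± 0.13). The heat shock list had 1 fall, HSPB1 (-0.60 ± 0.12), and 0 rises among 17 genes, as adjusted over the list alone (camera adjusted p = 0.844). The cholesterol synthesis genes IDI1 (0.87 ± 0.11) and INSIG1 (0.59 ± 0.15) were higher with Ad-E2F-1 alone than with Ad-LacZ plus doxorubicin, 2 of 20 sterol genes, as adjusted over the list alone (median 0.13, camera adjusted p = 0.109). Among 30 immediate early genes 3 rose there and 0 fell, as adjusted over the list alone (camera adjusted p = 0.176), namely CCN1 (1.18 ± 0.11), NR4A2 (0.67 ± 0.16) and KLF2 (0.53 ± 0.13). Of 19 MAPK output genes 1 rose, ETV5 (0.47 ± 0.11), and 3 fell, 2 and 3 adjusted over the list alone (camera adjusted p = 0.873), with TFPI2 at -0.64 ± 0.11.

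When doxorubicin was added to Ad-E2F-1, 2 of 30 immediate early genes rose, KLF4 (0.85 ± 0.17) and KLF10 (0.56 ± 0.12), and 2 fell, CCN1 and KLF6 (-0.80 ± 0.12), with 3 and 2 adjusted over the list alone (median 0.022, mean -0.029 and a downward camera direction, adjusted p = 0.66). That KLF6 value is from its probe set of highest mean, while the KLF6 probe set lower than with either single treatment differed by -1.13 ± 0.15 here. In the unfolded protein and ATF4 list CALR (0.90 ± 0.18) and CEBPB (0.54 ± 0.11) rose, 2 of 37, and 0 fell, with 3 of each adjusted over the list alone (median 0.029, camera adjusted p = 0.988). TFPI2 (0.81 ± 0.11) was the 1 rise among 19 MAPK output genes, with 3 of each adjusted over the list alone (median -0.17, camera adjusted p = 0.191). SRGN (0.82 ± 0.13) was the 1 rise among 9 immune markers, and the 1 adjusted over the list alone (median -0.10, mean 0.080 and an upward camera direction, adjusted p = 0.988). With doxorubicin added, 0 members of the sterol, heat shock, ribosomal protein, drug transport, histone, epithelial and fibroblast lists passed limma's threshold over all probe sets, and 1 drug transport and 1 histone gene rose adjusted over the list alone (camera adjusted p-values of 0.945, 0.844, 0.552, 0.88, 0.421, 0.988 and 0.945).

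Of 17 drug transport genes the efflux pump gene ABCG2 rose (0.73 ± 0.16) and ABCC5 fell (-0.54 ± 0.13) with Ad-E2F-1 alone against Ad-LacZ plus doxorubicin, as adjusted over the list alone (camera adjusted p = 0.776). The linker histone gene H1-2 was the 1 fall among 12 histone genes (-0.58 ± 0.13, 1 adjusted over the list alone, camera adjusted p = 0.671), and 0 of 51 ribosomal protein genes passed (median -0.064, camera adjusted p = 0.0608, 0 adjusted over the list alone). In the extracellular matrix and TGF-beta list 2 of 35 genes rose, CCN1 and CCN2, and 2 fell, INHBA and the integrin gene ITGA5 (-0.67 ± 0.14), with 3 of each adjusted over the list alone (median 0.005, mean -0.014 and an upward camera direction, adjusted p = 0.943). In the melanocyte list 1 gene rose, LEF1 (0.74 ± 0.12), and 2 did adjusted over the list alone (median 0.15, camera adjusted p = 0.0969). Marker lists of other cell types were not called in that comparison: KRT18 was the 1 fall among 7 epithelial markers (-0.38 ± 0.085, 1 rise and 2 falls adjusted over the list alone, camera adjusted p = 0.42), SRGN, a proteoglycan gene, the 1 fall among 9 immune markers (-0.85 ± 0.13, 1 adjusted over the list alone, camera adjusted p = 0.443), and 0 of 9 fibroblast markers passed, also adjusted over the list alone (median 0.030, mean -0.021 and a downward camera direction, adjusted p = 0.945).

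E2F1 read near 1 level in all groups. One explanation was that the arrays labelled combination came from cells with no more E2F activity than those labelled Ad-LacZ plus doxorubicin. The mean log2 signal of the G1/S list was 9.058 and 9.064 on the former and 8.724 and 8.722 on the latter (fry adjusted p = 0.000456). These array means go against that explanation, as far as RNA of E2F targets shows it, but the p-value adds no independent weight. Camera with an estimated correlation (adjusted p = 0.0513), which sets the list against all other genes, was the first test. The cyclin E genes (limma adjusted p = 0.000411) and then camera again followed. Fry was made the test after its value was seen because it asks only whether the list itself was higher. What raised these genes, the vector or another difference between the cells, stays open. That the E2F1 probe sets lie outside the part of E2F1 in the vector stays open too: the smallest adjusted p of an E2F1 probe set for a vector difference was 0.707, while cyclin E genes rose. A low level of the vector's transcript, or its loss by the time of harvest, may also account for it and was not tested.

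The oxidative phosphorylation list had a higher median when doxorubicin was added to Ad-E2F-1. A bias that follows signal level is argued against by matched lists, since the list median of 0.14 lay at percentile 100 of 10000 lists of like size and signal (range of the central lists -0.040 to 0.079). Scaling of the arrays left a median of at least 0.111, and leaving out any array a median of at least 0.142. Leaving out an array of Ad-LacZ plus doxorubicin cannot change this median, so only the arrays of the other groups test it. A response to the drug is a hypothesis that stays open, with an adjusted p of 0.11 for the list with an estimated correlation.

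The G2/M list shifted down by median from Ad-E2F-1 alone to the combination and again to Ad-LacZ plus doxorubicin, with 9 and 3 of 61 members past the threshold in these steps. The mean log2 signal of the list was 9.048 and 9.056, 8.756 and 8.774, and 8.564 and 8.584 on the arrays of these groups in that order. The order thus held on these arrays. With an estimated correlation the camera adjusted p was 0.0513 and 0.0819, so whether the order holds beyond these arrays is not settled. Matched lists argue against a bias with signal level, since the list median lay at percentile 0 for the drug step and at percentile 100 for the vector step, and each scaling kept at least 0.96 of either step. A like shift of all proliferation genes is argued against by the G1/S list, whose median lay 0.298 above that of the G2/M list when doxorubicin was added (permutation test over genes with 100000 resamples, p = 2e-05, with genes not independent of each other). A drug effect on mitotic genes that leaves the replication genes in place may account for this, as a hypothesis, since it was found and tested on the same arrays.

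CCN1, CCN2 and AMOTL2, known targets of the coactivators YAP and TAZ, fell when doxorubicin was added. If lower output of YAP and TAZ caused this, the other genes of a target list fixed before the test should fall too. Among 16 such genes 9 were negative, 1 passed (ASAP1, -0.69 ± 0.14), the median was -0.20 and the camera p was 0.0702. The test as first written took any p of 0.05 or more as evidence against the hypothesis. That reading was given up after the p was seen, because a p that misses the threshold with a negative median does not show that the genes stayed in place, so the test leaves the hypothesis open and does not favour it.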
